A study of Mus musculus with 10 samples.

How the data were processed

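RNA-seq was performed on polyadenylated RNA from purified tumour-associated macrophages, with RNA extracted by a column kit for small samples, per the labels' protocols. The 10 libraries form 2 groups of 5 by the antibody named in the labels. Replicate numbers follow the order of deposition and pair nothing, and the labels give no batch, day or litter. The authors aligned reads with GSNAP to the mouse genome build GRCm38, per the submitters' processing notes. The version of the aligner, the annotation release and the counting tool are not given in the sources used here, nor is whether counting used strand.

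The deposited counts are whole numbers of reads aligning uniquely to each gene model, per the file headers, with gene models named by Entrez identifier. Because only unique alignments were counted, near-identical gene copies can lose or share reads. The deposited RPKM values (reads scaled to gene length and library size) were adjusted by the authors with a size factor per library, per the file headers. Each library's RPKM equalled its counts times a per-gene factor and a single library factor, to within a relative deviation of 2.9e-13. The RPKM values were used only to recover those library factors for an alternative normalization.

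Of 36528 gene identifiers, 31049 were named from RefSeq's table for GRCm38.p6 and 78 from GENCODE M21, and 5401 stayed unnamed, holding 2.14% to 2.65% of the counts of a library. Unnamed genes stayed in library sizes and tests. Coordinates are those of RefSeq on GRCm38.p6. No 2 libraries agreed within sampling noise (the smallest chi-square per degree of freedom was 29.0), and Pearson correlations of log2 CPM across genes lay between 0.992 and 0.999.

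Genes were kept by edgeR's filterByExpr with the treatment group, which left 13588. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts, with TMM normalization, robust dispersion estimates, treatment as the only term and Benjamini-Hochberg adjustment at 0.05. All edgeR p-values are two-sided. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic and is approximate. CPM values use TMM library sizes and are given as mean ± SD over 5 libraries. The square root of the common dispersion was 0.159. Counts were simulated for the 13588 genes from these libraries' means, dispersions and sizes, with 200 changed genes in 3 runs. The changed genes were drawn among those with a mean of at least 2 CPM. On these counts the test recovered 94.7% of 2-fold changes and 69.7% of 1.5-fold changes, and 5.01% of calls were false. Genes were simulated independently of each other, so these rates may not carry over to genes that vary together or to lower expression.

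Before the data were examined, 16 gene lists and 15 lists of cell type markers were fixed from general knowledge, along with the design, the alternatives and the rule for named genes. The rule names Mertk, the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 1 (leaving out unnamed, predicted and pseudogene symbols), the 4 members of smallest p per gene list and the 2 of smallest p per marker list. This gave 102 genes. Other genes are named only where the text says that they were chosen after their values were seen. List members were counted with adjustment over all genes and over the list alone. Shifts were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists with at least 2 tested members, and again with an estimated correlation. With the estimated correlation no list passed. The test fry, which asks whether a list's genes move on balance in a given direction without comparing them with other genes, was a further alternative. List scores are mean log2 CPM values with a prior count of 2, compared by an exact permutation test over all 252 assignments, whose smallest p is 0.00794. Library measures were compared in the same way, with scipy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

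The alternatives were RLE size factors, upper quartile normalization, no filter, a filter of 5 CPM in 5 libraries, leaving out each library, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom with quality weights, an adjusted p under 0.01, a fold of at least 2, and for list scores a prior count of 0.5 and the median over members. Added after seeing the data were the authors' size factors, offsets for transcript length and GC content (natural splines with 4 degrees of freedom per library, from the longest GENCODE M21 transcript of each gene), the monocyte marker score as a covariate, and a fit on 8 libraries without anti-MerTK replicates 2 and 5. Replicate 2 lay farthest out on the first principal component, and replicate 5 had the highest scores among the anti-MerTK libraries for markers of neutrophils, T cells and fibroblasts. These scores were 2.89, 1.11 and 1.65 in anti-MerTK replicate 5, and 1.74, 0.79 and 1.64 in anti-gp120 replicate 2, which was kept. Before TMM scaling, depths of 33159858 to 46108687 counts put 1 CPM at over 33 reads in each library. The CPM values given here use TMM library sizes, so the reads behind 1 CPM differ from this and can be fewer.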

Results

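Tumour-associated macrophages were purified from mice bearing MC-38 tumours, which grow from a colon carcinoma line derived from C57BL mice. The mice had received an antibody against MerTK or, as the comparison group, an antibody against gp120, an envelope protein of HIV. MerTK is a receptor tyrosine kinase through which macrophages bind and engulf apoptotic cells. Polyadenylated RNA was profiled by sequencing 24 h after treatment, in 5 libraries per group. The libraries held 33159858 to 46108687 counted reads, and 16475 to 18090 genes had a count in each. Genes with a count numbered 17829.8 ± 284 after anti-MerTK and 17503.6 ± 609 after anti-gp120 (SD, n = 5 per group, two-sided exact permutation p = 0.333). The share of counts from mitochondrial genes was 0.612% ± 0.0404 and 0.711% ± 0.117 (SD, n = 5 per group, exact permutation p = 0.111). The labels do not say whether the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical.

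The comparison asks which transcripts of these macrophages differed 24 h after the antibody against MerTK. Interferon-stimulated genes made up the clearest group among the higher genes. Of 45 tested members of the type I interferon response list, 39 were higher after anti-MerTK and 0 were lower. Over all 13588 tested genes, 438 changed, 251 higher and 187 lower, in edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05. A rise of at least 2-fold was seen for 62 genes and a fall of at least 2-fold for 5. The median log2 fold change was 0.65 among the higher genes and -0.43 among the lower genes. The groups did not overlap for 811 of all 13588 tested genes (5.97%), where chance gives 0.794%. An unadjusted p under 0.05 was reached by 2840 genes. Single libraries weighed on the counts: 131 genes changed without anti-gp120 replicate 2, 70 without anti-gp120 replicate 4, 113 without anti-MerTK replicate 1, 154 without anti-MerTK replicate 2, 124 without anti-MerTK replicate 3 and 243 without anti-MerTK replicate 4. Without anti-gp120 replicate 3 the higher genes numbered 156, and without anti-MerTK replicate 5 the lower genes numbered 284. In settings added after seeing the data, 204 genes changed in 8 libraries and 12 with a score of monocyte markers as a covariate, all 12 higher. That score correlated with treatment across the libraries (r = 0.64), so the covariate can take up part of the treatment difference. The lost calls therefore do not show that monocytes caused the changes. Of the 38 named genes that passed, 19 kept their call in 8 libraries, and with the covariate only Marco, Isg15, Isg20 and Oas1g did.

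**Figure D1:**
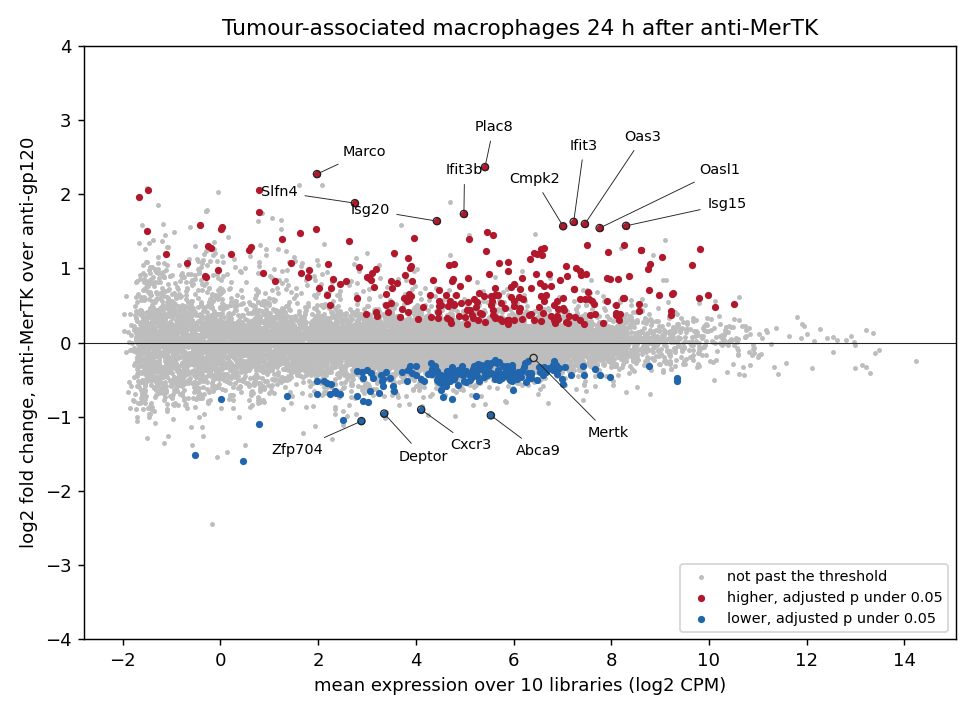
Log2 fold change of each tested gene (anti-MerTK over anti-gp120) against its mean expression in log2 CPM over the 10 libraries. Red points are the 251 higher genes and blue points the 187 lower genes at an adjusted p under 0.05, grey points the other genes, and circled points are labelled.

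Mertk itself, the gene of the antibody's target (Entrez 17289, GRCm38 chromosome 2, 128698915 to 128803162), gave 91.1 ± 14.3 CPM (counts scaled to library size) after anti-gp120 and 78.9 ± 4.96 CPM after anti-MerTK (SD, n = 5). Its log2 fold change was -0.21 (SE 0.10), which did not pass the test in edgeR (adjusted p = 0.263). All 5 anti-MerTK libraries lay below the mean of the anti-gp120 libraries, and the groups overlapped. The antibody binds the protein, so this transcript level does not measure how much receptor was blocked.

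Of the 50 largest rises, 19 were on the type I or gamma interferon lists, and the 10 largest with a mean log2 CPM of at least 1 are given here. Plac8, a gene expressed in monocytes and plasmacytoid dendritic cells, rose from 13.8 ± 10.8 to 71.4 ± 34.4 CPM (log2 fold change 2.37, SE 0.50, edgeR adjusted p = 0.0346). Marco, a scavenger receptor of macrophages (chromosome 1, 120474538 to 120505024), rose from 1.33 ± 0.306 to 6.41 ± 1.93 CPM (log2 fold change 2.27, SE 0.23, edgeR adjusted p = 0.00355). Isg15, a ubiquitin-like protein induced by interferon (chromosome 4, 156199424 to 156200818), rose from 158.8 ± 40.02 to 473 ± 87.4 CPM (log2 fold change 1.57, SE 0.18, edgeR adjusted p = 0.00441). Isg20, an exonuclease acting on viral RNA, rose 3.11-fold from 10.5 ± 2.70 CPM. The remaining members of the 10 largest rises were Slfn4 (3.68-fold), Ifit3b (3.33-fold), Ifit3 (3.09-fold), Oas3 (3.03-fold), Cmpk2 (2.97-fold) and Oasl1 (2.92-fold), with edgeR adjusted p between 0.00875 and 0.0430. Each of these 10 genes was higher in 5 of 5 anti-MerTK libraries than the anti-gp120 mean. Ifit3 and Ifit3b are near-identical copies whose reads could be split between them, so their separate values are uncertain. Without the expression filter, Plac8 and Slfn4 had adjusted p of 0.0905 and 0.105, and Slfn4 had 0.0548 with limma-voom. Plac8 did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.103, 0.0629 and 0.109) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.0857, 0.0937 and 0.0566). Slfn4 did not pass without anti-gp120 replicates 2, 3, 4 or 5 (adjusted p = 0.114, 0.0799, 0.126 and 0.0543) or anti-MerTK replicates 1 or 3 (adjusted p = 0.0957 and 0.0837). Oas3 did not pass without anti-gp120 replicate 4 (adjusted p = 0.0555).

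**Figure D2:**
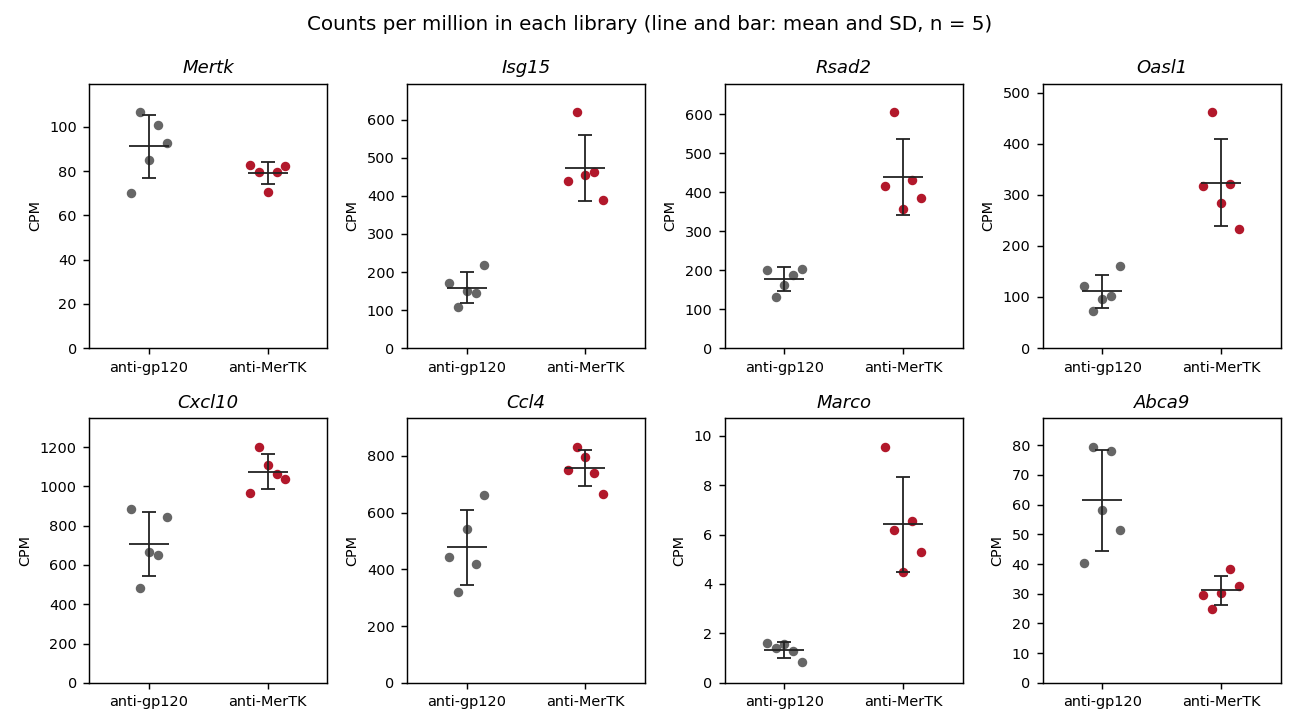
CPM of 8 named genes in each library, with the mean (line) and SD (bar) of 5 libraries per group. For Isg15, Rsad2, Oasl1, Marco, Cxcl10, Ccl4 and Abca9 the points of the groups do not overlap, while those of Mertk do.

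Members of the type I interferon response list rose together. Their median log2 fold change was 1.005, and all 45 had a positive estimate. Rsad2, an antiviral enzyme also called viperin, rose from 177 ± 30.1 to 439 ± 97.3 CPM (log2 fold change 1.31, SE 0.16, edgeR adjusted p = 0.00441). Oas1g, of the family of 2'-5' oligoadenylate synthetases, rose from 25.9 ± 3.98 to 60.8 ± 11.1 CPM (log2 fold change 1.23, SE 0.14). Adjusted over the list alone, 43 members were higher. Members that did not pass over all genes included Parp14, Eif2ak2, Samd9l, Slfn8 and Trim25, with log2 fold changes of 0.65, 0.51, 0.49, 0.64 and 0.07 (chosen for naming after their values were seen). The mean log2 CPM of the list was higher in each anti-MerTK library than in any anti-gp120 library, by 1.03 between group means (exact permutation p = 0.00794, the smallest that 252 assignments give, and 0.0741 after adjustment over 28 lists). The list shifted upward relative to other genes in camera with its preset correlation of 0.01 (adjusted p = 1.4e-90). The correlation estimated between its genes was 0.78, so the preset makes that p-value too small. With the estimated correlation the adjusted p in camera was 0.0895, and it was 0.00994 in fry. Without anti-gp120 replicate 4, 24 members passed. The markers of monocytes were also higher in these libraries, by 0.85 in mean log2 CPM (exact permutation p = 0.0397, adjusted 0.222). With that monocyte score as a covariate, a setting added after seeing the data, 6 of the 45 members passed, while all 45 estimates stayed positive and their median log2 fold change was 1.116.

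**Figure D3:**
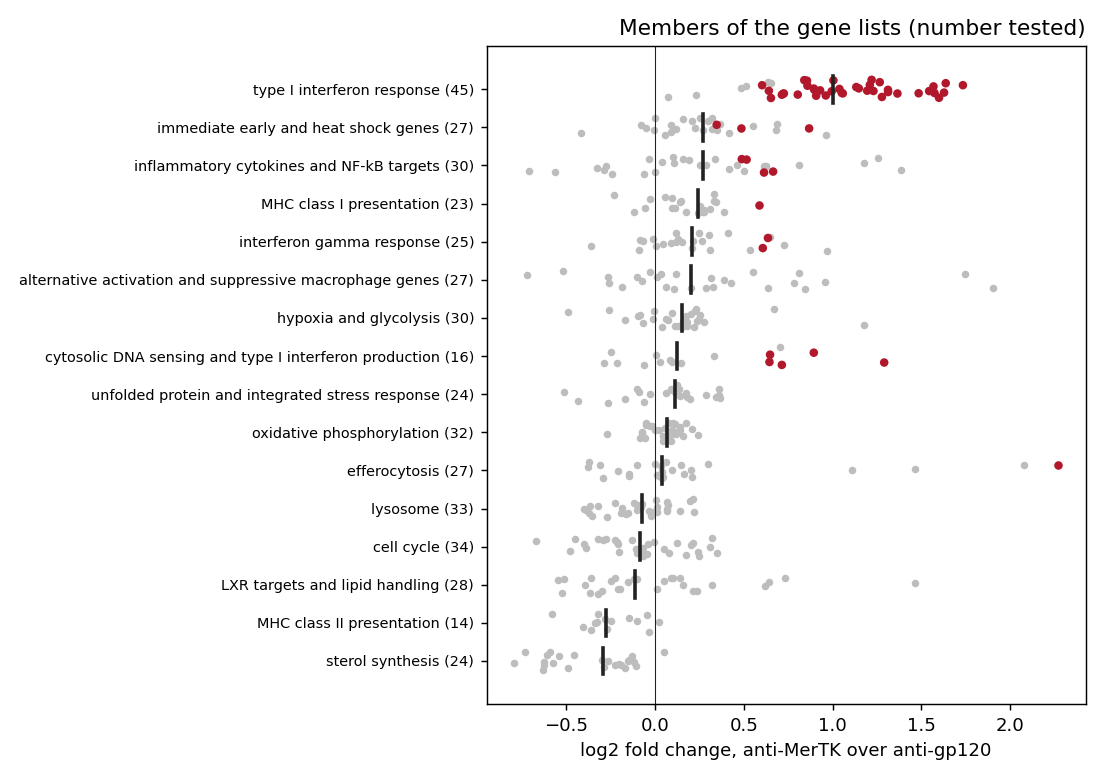
Log2 fold change (anti-MerTK over anti-gp120) of the tested members of the 16 gene lists, with the number tested in brackets, with vertical bars for list medians. Red points passed an adjusted p under 0.05 in the higher direction and grey points did not pass.

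Genes of the interferon gamma response list moved less. Of 25 tested members, 2 were higher and 0 lower, and the same number was higher when adjusted over the list alone. Fcgr1, the high-affinity Fc gamma receptor I, rose from 792 ± 115 to 1230 ± 206 CPM (log2 fold change 0.64, SE 0.13, edgeR adjusted p = 0.0247). Cxcl10, a chemokine that attracts T cells, rose from 706 ± 162 to 1075 ± 87.7 CPM (log2 fold change 0.61, SE 0.14, edgeR adjusted p = 0.0426). Cxcl11 and Il12rb1 had log2 fold changes of 0.97 and 0.54 and did not pass (edgeR adjusted p = 0.120 and 0.252). The list shifted upward with the preset correlation (adjusted p = 0.00180), but had an adjusted p = 0.779 with an estimated correlation and 0.390 in fry. The shift also missed the threshold without anti-gp120 replicate 2 (adjusted p = 0.0682). Fcgr1 did not pass without anti-gp120 replicates 2 or 4 (adjusted p = 0.0554 and 0.0781) or anti-MerTK replicates 1 or 3 (adjusted p = 0.0624 and 0.0575). Cxcl10 did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.0619, 0.0756 and 0.120) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0795, 0.0947, 0.102 and 0.0689).

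Among genes of cytosolic DNA sensing and type I interferon production, 5 of 16 tested were higher and 0 lower. Ifi204, a DNA-binding protein of the PYHIN family, rose from 332 ± 44.8 to 544 ± 77.7 CPM (log2 fold change 0.71, SE 0.12, edgeR adjusted p = 0.0115). Cgas, the enzyme that makes cyclic GMP-AMP on binding DNA, rose from 19.1 ± 1.41 to 29.9 ± 6.11 CPM (log2 fold change 0.64, SE 0.13). Zbp1 and Ikbke rose by log2 fold changes of 0.89 and 0.65. The 5th was Ifnb1, the gene of interferon beta, at 0.865 ± 0.438 and 2.11 ± 0.535 CPM (log2 fold change 1.29, SE 0.30, edgeR adjusted p = 0.0430, named after its value was seen). Sting1, the adaptor downstream of cyclic GMP-AMP, had a log2 fold change of 0.10 (SE 0.12), and P2rx7, an ATP-gated channel, of -0.22 (SE 0.07, edgeR adjusted p = 0.110), both also named after their values were seen. Adjusted over the list alone, 7 members were higher and 1 lower. Ifi204 and Zbp1 also stand in the type I interferon list. The list's camera shift had an adjusted p = 0.000332 with the preset correlation and an adjusted p = 0.289 with an estimated correlation, and 0.0207 in fry. Cgas did not pass without anti-gp120 replicates 2 or 4 (adjusted p = 0.0584 and 0.0686) or anti-MerTK replicates 1 or 3 (adjusted p = 0.0558 and 0.0626). Zbp1 did not pass without anti-gp120 replicate 4 (adjusted p = 0.0791) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0635, 0.0547, 0.0575 and 0.0524). Ikbke did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.0892, 0.0633 and 0.0817) or anti-MerTK replicates 1 or 4 (adjusted p = 0.0789 and 0.0597). Ifnb1 did not pass without anti-gp120 replicates 2, 3, 4 or 5 (adjusted p = 0.107, 0.0620, 0.116 and 0.0601) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0793, 0.0588, 0.0927 and 0.0819).

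Inflammatory cytokines and NF-kB targets had 4 of 30 tested members higher and 0 lower. Tnfsf9, the ligand of the T-cell receptor 4-1BB, rose from 48.5 ± 6.92 to 74.2 ± 5.85 CPM (log2 fold change 0.61, SE 0.10, edgeR adjusted p = 0.0114). The chemokines Ccl3 and Ccl4 rose by log2 fold changes of 0.52 and 0.66, and the cytokine Il18 by 0.49, with edgeR adjusted p between 0.0328 and 0.0485. Adjusted over the list alone, 11 were higher and 1 lower. The list shift had an adjusted p = 0.000332 with the preset correlation and an adjusted p = 0.463 with an estimated correlation, and 0.0666 in fry. With length and GC offsets, Ccl3 and Ccl4 did not pass (adjusted p = 0.114 and 0.0587), and Ccl4 had 0.0735 without the expression filter and 0.0505 with the authors' size factors. Tnfsf9 passed with each single library left out. Ccl3 did not pass without anti-gp120 replicates 1, 2, 3 or 4 (adjusted p = 0.0550, 0.0926, 0.0657 and 0.0864) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0937, 0.0603, 0.0927 and 0.0509). Ccl4 did not pass without anti-gp120 replicates 1, 2, 3 or 4 (adjusted p = 0.0742, 0.0737, 0.0633 and 0.139) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.106, 0.111, 0.118 and 0.0770). Il18 did not pass without anti-gp120 replicates 2, 4 or 5 (adjusted p = 0.0913, 0.102 and 0.0543) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0606, 0.0774, 0.0864 and 0.0687).

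In the MHC class I list, 1 of 23 tested members was higher. This was H2-T22, a non-classical class I molecule, which rose from 149 ± 25.4 to 224 ± 39.8 CPM (log2 fold change 0.58, SE 0.14, edgeR adjusted p = 0.0434). H2-T22 did not pass without anti-gp120 replicates 1, 2, 3 or 4 (adjusted p = 0.0630, 0.0935, 0.0610 and 0.121) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0979, 0.0811, 0.0710 and 0.0753). Erap1, Tapbp and Psmb10, which act in peptide processing or loading, had log2 fold changes of -0.23, 0.33 and 0.34 and did not pass. Erap1 passed with DESeq2, limma-voom, 1 surrogate variable and the 5 CPM filter (adjusted p = 0.00194, 0.0362, 0.0400 and 0.0396). Tapbp passed without anti-gp120 replicate 5 (adjusted p = 0.0387). Adjusted over the list alone, 1 was higher and 1 lower. The class I list shifted upward (adjusted p = 0.000819 with the preset correlation, adjusted p = 0.698 with an estimated correlation, 0.263 in fry). In the MHC class II presentation list 0 of 14 members passed, over all genes or over the list alone. Its median log2 fold change was -0.28, with H2-Aa at 11482 ± 2991 and 8658 ± 2369 CPM (log2 fold change -0.41, SE 0.21, edgeR adjusted p = 0.293), and H2-Oa, H2-DMa and H2-Ob at -0.58, -0.28 and -0.33. The class II shift was downward (adjusted p = 0.0117 with the preset correlation, adjusted p = 0.750 with an estimated correlation, 0.348 in fry). It missed the threshold without anti-gp120 replicate 5 (adjusted p = 0.169) and without anti-MerTK replicate 5 (adjusted p = 0.0610). The class II shift also missed it in 8 libraries (adjusted p = 0.0714), and with the monocyte covariate its direction reversed (adjusted p = 0.769).

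The efferocytosis list, with receptors and bridging molecules for apoptotic cells, had 1 of 27 tested members higher, Marco, and 0 lower (camera adjusted p = 0.262), and 2 higher over the list alone. Cd36, Adgrb1 and Itgav had log2 fold changes of 1.46, 2.08 and -0.31 and did not pass (edgeR adjusted p = 0.117, 0.0690 and 0.114). Cd36 passed without anti-gp120 replicate 1 (adjusted p = 0.0436). Adgrb1 was barely detected, at 0.116 ± 0.115 CPM after anti-gp120 and 0.486 ± 0.235 CPM after anti-MerTK, so its fold change is uncertain. It passed without anti-gp120 replicate 3 (adjusted p = 0.0401) or anti-MerTK replicate 5 (adjusted p = 0.0279). Of 28 LXR targets and lipid handling genes 0 passed, with Lpl, Nr1h3 and Pparg at 0.62, 0.64 and 0.73 and Npc1 at -0.37 (camera adjusted p = 0.767), and over the list alone 1 was higher and 1 lower. Lpl passed with DESeq2, limma-voom and 1 surrogate variable (adjusted p = 0.00467, 0.0408 and 0.0358). It also passed with upper quartile normalization and with length and GC offsets (adjusted p = 0.0483 and 0.0460). Npc1 passed without anti-gp120 replicates 1 or 5 (adjusted p = 0.0450 and 0.0494). Pparg passed without anti-MerTK replicate 5 (adjusted p = 0.0386). Of 24 sterol synthesis genes 0 passed, over all genes or over the list alone, while 23 had a negative estimate and the median log2 fold change was -0.29. Stard4, a sterol carrier, Sc5d and Fdft1 had log2 fold changes of -0.73 (SE 0.24), -0.59 (SE 0.19) and -0.27 (SE 0.08), with edgeR adjusted p of 0.115, 0.102 and 0.101. Stard4 passed without anti-gp120 replicate 5 (adjusted p = 0.0424). Sc5d passed without anti-gp120 replicate 5 (adjusted p = 0.0398). Fdft1 passed without anti-gp120 replicate 5 (adjusted p = 0.0232). The sterol list shifted downward with the preset correlation (adjusted p = 1.76e-05), and its adjusted p = 0.698 with an estimated correlation and 0.254 in fry.

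Of 27 immediate early and heat shock genes, which respond to tissue dissociation and handling, 3 were higher and 0 lower. Hspa1a and Hspa8, both heat shock chaperones, rose by log2 fold changes of 0.87 (SE 0.20) and 0.35 (SE 0.09), and Dusp1, a phosphatase of MAP kinases, by 0.49 (SE 0.12). Egr1 was at 161 ± 39.0 and 259 ± 46.5 CPM (log2 fold change 0.68, edgeR adjusted p = 0.0559). Egr1 passed without anti-MerTK replicate 5 (adjusted p = 0.0342). It also passed with DESeq2, limma-voom and 1 surrogate variable (adjusted p = 0.00219, 0.0247 and 0.0350). Upper quartile normalization, the 5 CPM filter and the length and GC offsets gave Egr1 an adjusted p of 0.0477, 0.0497 and 0.0281. Adjusted over the list alone, 11 were higher. The mean log2 CPM of the list was 7.59 ± 0.149 after anti-MerTK and 7.32 ± 0.0934 after anti-gp120 (SD, n = 5), without overlap between the groups. Its exact permutation p was 0.00794 (adjusted 0.0741), as for the type I interferon list. The shift had an adjusted p = 3.95e-06 with the preset correlation and an adjusted p = 0.312 with an estimated correlation, and 0.0342 in fry. With length and GC offsets, Hspa1a and Dusp1 did not pass (adjusted p = 0.0763 and 0.0795), and Hspa1a had 0.0966 without the expression filter. Hspa1a did not pass without anti-gp120 replicates 1, 2, 3, 4 or 5 (adjusted p = 0.0568, 0.0715, 0.0582, 0.0962 and 0.0656) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0755, 0.0957, 0.104 and 0.0687). Hspa8 did not pass without anti-gp120 replicates 1, 2, 3 or 4 (adjusted p = 0.0690, 0.112, 0.0672 and 0.138) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0770, 0.111, 0.127 and 0.0687). Dusp1 did not pass without anti-gp120 replicates 1, 2, 3, 4 or 5 (adjusted p = 0.0637, 0.105, 0.0572, 0.101 and 0.0619) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0979, 0.0771, 0.0946 and 0.0687).

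Of the other gene lists, 0 members passed over all genes or over the list alone. These were lysosome (33 tested, median log2 fold change -0.07, camera adjusted p = 0.150), alternative activation and suppressive macrophage genes (27 tested, 0.20, 0.317), cell cycle (34 tested, -0.08, 0.517), hypoxia and glycolysis (30 tested, 0.15, 0.0807), unfolded protein and integrated stress response (24 tested, 0.11, 0.0807) and oxidative phosphorylation (32 tested, 0.07, 0.205). Their members with the smallest p included Arg1 at 379 ± 184 and 681 ± 306 CPM (log2 fold change 0.85, SE 0.36, edgeR adjusted p = 0.211), Folr2 (0.78), Man2b1 (-0.39), Pcna (0.24), Hk2 (0.25), Creld2 (0.34) and Ndufs1 (-0.27). Man2b1 passed without anti-gp120 replicate 1 (adjusted p = 0.0318). Ndufs1 passed without anti-gp120 replicate 5 (adjusted p = 0.0309) or anti-MerTK replicate 5 (adjusted p = 0.0422). The shift of lysosome passed without anti-gp120 replicate 1 (adjusted p = 0.0408) or anti-MerTK replicate 5 (adjusted p = 0.0287). The shift of alternative activation and suppressive macrophage genes passed without anti-MerTK replicate 2 (adjusted p = 0.0486). The shift of cell cycle passed without anti-gp120 replicate 4 (adjusted p = 0.0431) or anti-MerTK replicate 1 (adjusted p = 0.0246). The shift of hypoxia and glycolysis passed without anti-gp120 replicate 1 (adjusted p = 0.000809) or anti-MerTK replicates 2, 3 or 4 (adjusted p = 0.0390, 0.0389 and 0.00385). With the monocyte covariate it passed in the reversed direction (adjusted p = 0.00694). The shift of unfolded protein and integrated stress response passed without anti-gp120 replicate 2 (adjusted p = 0.0460) or anti-MerTK replicates 1 or 2 (adjusted p = 0.0246 and 0.0339). The shift of oxidative phosphorylation passed without anti-gp120 replicate 3 (adjusted p = 0.0193).

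The lower genes belonged to none of the fixed gene lists: 53 of the 438 changed genes were on a gene list, and all 53 were higher. Abca9, an ABC transporter, fell from 61.5 ± 17.0 to 31.1 ± 4.93 CPM (log2 fold change -0.98, SE 0.18, edgeR adjusted p = 0.0212). Cxcr3, a chemokine receptor that binds Cxcl10, fell from 22.4 ± 5.64 to 11.97 ± 2.01 CPM (log2 fold change -0.90, SE 0.18, edgeR adjusted p = 0.0273). Pgap1, an enzyme of GPI anchor maturation, fell from 29.4 ± 3.79 to 17.6 ± 1.02 CPM (log2 fold change -0.74, SE 0.09, edgeR adjusted p = 0.00441). Zfp704, Deptor, Ago4, Agmo, Fbxl20, Tmem150b and Cdh1 fell by log2 fold changes of -1.06, -0.96, -0.81, -0.79, -0.76, -0.72 and -0.72, and all 5 anti-MerTK libraries lay below the anti-gp120 mean for each of the 10. The 5 genes lower by at least 2-fold were Zfp704 and, named after their values were seen, Ifnlr1, Gpr82, Sult1a1 and 0610040J01Rik. Ifnlr1, the receptor chain for interferon lambda, was at 2.01 ± 0.864 and 0.658 ± 0.235 CPM. Ago4 and Pgap1 passed with each single library left out. Abca9 did not pass without anti-gp120 replicate 4 (adjusted p = 0.0603) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.0625, 0.0506 and 0.0618). Cxcr3 did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.0618, 0.0557 and 0.0791) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.0628, 0.0667 and 0.0740). Zfp704 did not pass without anti-gp120 replicates 2 or 4 (adjusted p = 0.0870 and 0.0759) or anti-MerTK replicates 2, 3 or 4 (adjusted p = 0.0771, 0.0905 and 0.0639). Deptor did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.0800, 0.0528 and 0.0812) or anti-MerTK replicates 1 or 3 (adjusted p = 0.0820 and 0.0811). Agmo did not pass without anti-gp120 replicates 2, 3, 4 or 5 (adjusted p = 0.0512, 0.0680, 0.0891 and 0.0544) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0642, 0.0516, 0.0746 and 0.0687). Fbxl20 did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.0847, 0.0594 and 0.0918) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.0843, 0.0559 and 0.0908). Tmem150b did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.0547, 0.0588 and 0.0798) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.0755, 0.0510 and 0.0864). Cdh1 did not pass without anti-gp120 replicate 2 (adjusted p = 0.0584) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.0672, 0.0510 and 0.0708). Ifnlr1 did not pass without anti-gp120 replicates 2 or 4 (adjusted p = 0.0686 and 0.0791) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.0795, 0.0547 and 0.0791).

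Lower genes had longer transcripts than the rest. The median length of the longest annotated transcript was 5188.5 bases over 180 lower genes with a match, 2718 over 228 higher genes and 3346 over genes that did not pass, and the median GC content was 44.2%, 51.0% and 49.7%. In the longest sixth of the genes the median log2 fold change was -0.14, and in the shortest sixth 0.08. With offsets for transcript length and GC content, a setting added after seeing the data, 126 genes were lower and 231 higher, and 95 of the 187 lower genes and 193 of the 251 higher genes passed in the same direction. Of the 38 named genes 31 kept their call, and Fbxl20, Ccl3, Ccl4, Hspa1a, Dusp1, Cox6a2 and Cd247 did not (adjusted p = 0.0580, 0.114, 0.0587, 0.0763, 0.0795, 0.0823 and 0.0667).

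**Figure D4:**
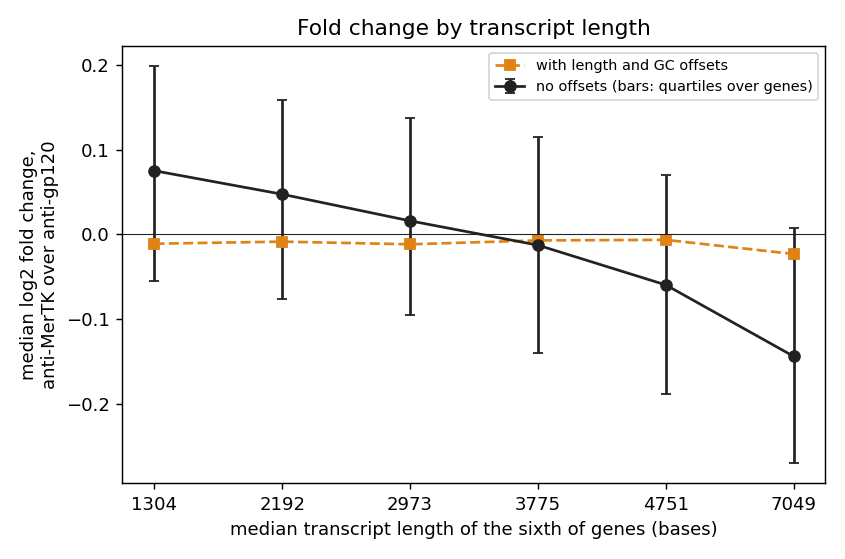
Median log2 fold change (anti-MerTK over anti-gp120) over equal sixths of the tested genes ordered by transcript length in bases, with bars for the quartiles over genes. Without offsets (black) the medians run from 0.08 in the shortest sixth to -0.14 in the longest, and with length and GC offsets (orange) from -0.01 to -0.02.

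Markers of the cell types that the purified samples could hold were examined beside these groups. Of 12 macrophage markers 1 was higher, Fcgr1, and Cd68 was at 874 ± 27.1 and 999.989 ± 57.0 CPM (log2 fold change 0.19, edgeR adjusted p = 0.122). Of 8 monocyte markers 1 was higher, Plac8, and 4 were higher adjusted over the list alone. Ccr2, at 186 ± 60.5 and 273 ± 36.0 CPM, did not pass over all genes (edgeR adjusted p = 0.165). The monocytes list shifted upward with the preset correlation (adjusted p = 0.000964), with an adjusted p = 0.487 with an estimated correlation, 0.109 in fry, and an adjusted p = 0.0565 without anti-MerTK replicates 2 and 5. Cd247, a chain of the T-cell receptor complex, fell from 5.65 ± 0.910 to 3.84 ± 0.481 CPM (edgeR adjusted p = 0.0483), as 1 of 6 tested T cell markers. Cdh1, the only tested member of the epithelial tumour cell list, fell from 46.5 ± 10.01 to 28.2 ± 3.66 CPM. Cox6a2, 1 of 4 tested plasmacytoid dendritic cell markers, rose from 2.98 ± 0.613 to 4.99 ± 1.03 CPM. No marker passed over all genes among neutrophils (3 tested), type 1 conventional dendritic cells (9), type 2 and migratory dendritic cells (8), NK and cytotoxic cells (4), B cells (2), eosinophils (2), fibroblasts (13) or endothelial cells (6). Camera adjusted p for these lists, macrophages, T cells and plasmacytoid dendritic cells lay between 0.128 and 0.767. The endothelial score was 2.11 ± 0.0657 after anti-MerTK and 1.83 ± 0.171 after anti-gp120 in mean log2 CPM (SD, n = 5, exact permutation p = 0.0159, adjusted 0.111), and fry gave the list an adjusted p = 0.0207, against 0.246 in camera. Adjusted over the list alone, 3 endothelial markers were higher and 1 lower, 2 plasmacytoid dendritic cell markers higher and 1 lower, and 1 marker of type 2 and migratory dendritic cells was lower. Markers of mast cells and basophils and of erythroid cells were too low to be tested. With length and GC offsets, Cd247 and Cox6a2 did not pass (adjusted p = 0.0667 and 0.0823), and Cd247 had 0.0511 without the expression filter. Cd247 did not pass without anti-gp120 replicates 1, 2 or 4 (adjusted p = 0.0654, 0.123 and 0.137) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0820, 0.108, 0.126 and 0.0702). Cox6a2 did not pass without anti-gp120 replicates 1, 2, 3 or 4 (adjusted p = 0.0652, 0.0995, 0.0718 and 0.0791) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.0795, 0.0957, 0.0837 and 0.0837). The shift of conventional dendritic cells type 1 passed without anti-MerTK replicate 5 (adjusted p = 0.0319), and that of fibroblasts without anti-MerTK replicate 5 (adjusted p = 0.0353).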

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

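Of 268 sets of 5 values (named genes, list scores and library measures, per group), 7 had a sample far from the other 4 by Dixon's test, where chance flags about 1 in 20 groups, here about 13. The tests of the length and GC offsets as the whole cause, of the monocyte covariate and of the monocyte scores were chosen only after the results were seen.

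Mertk was lowest in anti-MerTK replicate 3, at 6.14 log2 CPM against 6.31 to 6.37 in the other 4. Ifi204 was lowest in anti-gp120 replicate 2, at 7.995 log2 CPM against 8.38 to 8.52. Fdft1, an enzyme of sterol synthesis, was lowest in anti-gp120 replicate 5, at 5.05 against 5.39 to 5.46. Fap, a fibroblast marker, was lowest in the same library, at -1.75 against -0.61 to -0.29. Col1a1, a collagen of fibroblasts, was highest in anti-MerTK replicate 5, at 4.29 against -0.31 to 0.92, and S100a8, a neutrophil protein, was highest in the same library, at 0.74 against -2.24 to -1.60. The cell cycle score was highest in anti-MerTK replicate 1, at 5.40 against 5.04 to 5.07.

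The rise of type I interferon genes is the pattern most open to follow-up. In 100 splits of the 10 libraries into 5 and 5, the real split included, 1 gave as many changed genes (438, highest other 41). Likewise 1 gave as many in the more frequent direction (251, highest other 34) and 1 as many in the less frequent direction (187, highest other 14). For members of the type I interferon list 1 split gave as many (39, highest other 0). Each other split put libraries of both groups on both sides, which can widen the spread within a side, so only the rank is read. By that rank, chance is an unlikely source of these 4 counts. With the monocyte score as a covariate the list's median log2 fold change was 1.116 (quartiles 0.82 and 1.39) against 1.005 without it. The median estimate thus did not shrink. This cannot decide on a larger share of monocytes, because the score varied with treatment and its slope rests on the spread within 5 libraries per group. Anti-MerTK replicate 5 had the highest monocyte score (4.08) and the lowest type I score of its group (7.28). The calls fell to 6 of 45 while the median SE rose from 0.17 to 0.22, and over all genes the calls fell to 12. The score correlated with treatment (r = 0.64), which can widen the errors of the treatment estimate, and the cause of the lost calls was not tested. With length and GC offsets the median was 0.97 (quartiles 0.82 and 1.27). The average trend that they remove was small, with a median log2 fold change of 0.08 in the shortest sixth of genes. These offsets could thus not have removed the rise, and show only that the average trend does not account for it. A response to interferon in the macrophages after anti-MerTK remains as a hypothesis, found and tested on the same libraries.

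The fall of 187 genes with long, GC-poor transcripts may be partly technical. Their median log2 fold change was -0.43 without offsets and -0.34 with them (quartiles -0.44 and -0.26). The offsets remove only an average trend, and moved the median of the longest sixth of genes from -0.14 to -0.02. So small a step could not remove the fall of genes that were called for it. The comparison shows only that the average trend does not make up the whole fall. Whether length or GC content acted more strongly on single genes was not tested. Of the 187, 92 lost their call: their median moved from -0.39 to -0.27, while the median SE moved from 0.09 to 0.07, so the estimates shrank and the errors did not grow. Transcript lengths were known for 180 of the 187. Among these, the genes that lost their call had transcripts 1.45 times as long in the median as those that kept it (permutation p = 1e-04, the smallest that 10000 resamples give). However, the offsets lift long transcripts by construction (Spearman -0.94 between offset and length over the lower genes), so the ratio decides nothing. Whether the trend comes from RNA quality or from the treatment cannot be told apart: the rank correlation of transcript length with expression relative to the mean of the 10 libraries averaged -0.15 after anti-MerTK and 0.14 after anti-gp120 (exact permutation p = 0.0635). The groups overlapped: anti-gp120 replicates 2 and 4 had 0.42 and 0.36 and replicate 3 had -0.19, against -0.34 to -0.04 after anti-MerTK. The anti-gp120 mean was 0.07 without replicate 2, 0.08 without replicate 4 and 0.22 without replicate 3 (exact permutation p = 0.103, 0.103 and 0.00794). The correlation with GC content averaged 0.15 and -0.11 (exact permutation p = 0.0397), with p from 0.00794 to 0.0794 as each library was left out and under 0.05 only without anti-gp120 replicate 5 or anti-MerTK replicates 2 or 5.

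Monocyte markers were higher by 0.85 in mean log2 CPM over 8 markers (exact permutation p = 0.0397, adjusted 0.222 over the lists), which does not exclude chance. A larger share of monocytes among the purified cells could raise all of them. A score over 6 of the 8 markers was higher by 0.45 (exact permutation p = 0.286), with 4.17 in anti-MerTK replicate 5 and 2.64 in anti-MerTK replicates 3 and 4, against 2.08 to 3.26 after anti-gp120. The 5 libraries per group are too few to decide between a larger share of monocytes, monocyte-like expression in macrophages and chance. How the macrophages were sorted is not given in the sources used here.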

How the results depend on the processing

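No paired analysis was possible because the labels give no replicate numbers, and the numbers used here follow the order of deposition and pair nothing. The number of changed genes stayed within 1.5 times of 438 with RLE size factors (427), upper quartile normalization (448), no filter (388), the 5 CPM filter (454), the authors' size factors (418) and the length and GC offsets (357). It moved further in other settings. DESeq2 called 1152 genes (601 higher, 551 lower), limma-voom 1007 (511 and 496) and the fit with 1 surrogate variable 832 (457 and 375), and these shared 434, 436 and 438 genes with the main result. The 8 libraries gave 204 (152 and 52), the monocyte covariate 12 (12 and 0, with 2112 genes at an unadjusted p under 0.05), the adjusted p under 0.01 15 (13 and 2) and the 2-fold threshold 67 (62 and 5). The cause was not tested, except that the stricter thresholds lower the counts by construction. With each library left out the changed genes ranged from 70 to 654, the higher genes from 55 to 370, the lower genes from 15 to 284 and the higher type I interferon members from 24 to 42. The lowest values came without anti-gp120 replicate 4 and the highest without anti-MerTK replicate 5. The monocyte covariate left 6 type I interferon members past the threshold. All 45 members had a positive estimate in each of the 22 settings fitted. With the preset correlation, the camera shift of the type I list had adjusted p from 2.3e-110 to 1.8e-73 with a library left out. The preset lies far below the estimated correlation of 0.78, with which the adjusted p was 0.0895. Reversed directions came with the monocyte covariate for the MHC class II shift (adjusted p = 0.769) and the hypoxia and glycolysis shift (adjusted p = 0.00694), and the cause was not tested. The same covariate brought shifts past the threshold for cell cycle (adjusted p = 8.28e-05), fibroblasts (0.000632), conventional dendritic cells type 1 (0.0135) and T cells (0.0267), and the cause was not tested. The lysosome shift passed with the length and GC offsets (adjusted p = 0.0217) and in 8 libraries (0.0491), and without the expression filter those of hypoxia and glycolysis (0.0418) and the unfolded protein and integrated stress response (0.0465) passed. Of 38 named genes past the threshold, between 14 and 38 kept their call with a library left out, 38 with DESeq2, 31 with the offsets, 19 with 8 libraries and 4 with the monocyte covariate, and 0 changed sign in any of these. Among genes followed by name across the settings, 26 without a main call passed with DESeq2, 16 with 1 surrogate variable and 13 with limma-voom. Erap1, Lpl and Egr1 passed in all of these. No setting changed the depth, so what depth limits was not tested. The fry test lost the calls of the interferon gamma, inflammatory, MHC class I, MHC class II, sterol and monocyte lists, and gained that of the endothelial list.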

Other observations

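The 2 tests reported here, of the PYHIN family and of type I against gamma interferon genes, were chosen only after the results were seen, as were the genes named. Of 11 tested members of the PYHIN family, which are encoded in a cluster on chromosome 1, 9 were higher past the threshold (81.8%): Ifi214, Ifi205, Ifi206, Ifi213, Ifi211, Ifi209, Mndal, Ifi204 and Ifi203, with log2 fold changes from 1.54 to 0.49. Ifi207 (0.32, SE 0.11, edgeR adjusted p = 0.131) and Aim2 (0.03, SE 0.10, edgeR adjusted p = 0.903) did not. The members are close paralogs that can share reads, so single values are uncertain. Ifi204 was already counted in the type I interferon and DNA sensing lists, and Aim2 was tested in the latter. The family as a set was on no fixed list, and the share counted as high was set after the values were seen. No enrichment test was run, so a response of the family to interferon remains only a hypothesis.

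Single genes outside the naming rule are given as values only, with no test of any shared function. Ccl12, a monocyte-attracting chemokine, was at 231 ± 73.9 and 549 ± 128 CPM (log2 fold change 1.25, SE 0.22, edgeR adjusted p = 0.0198). An unnamed gene model has counts within 2% of those of Ccl12 in every library and was also called, so this locus is counted 2 times among the 438. Tnfsf10, the death ligand TRAIL, had a log2 fold change of 0.87, Il15 of 0.62, Adar of 0.56 and Mlkl, the effector of necroptosis, of 0.54. On the lower side stood the receptor genes Ifngr1 (252 ± 31.2 and 186 ± 22.5 CPM, log2 fold change -0.43, edgeR adjusted p = 0.0449) and Tgfbr1 (767 ± 134 and 536 ± 62.2 CPM, log2 fold change -0.52, edgeR adjusted p = 0.0453). Ccl12 did not pass without anti-gp120 replicate 4 (adjusted p = 0.0655) or anti-MerTK replicate 3 (adjusted p = 0.0515). Tnfsf10 did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.0554, 0.0526 and 0.0791) or anti-MerTK replicates 1 or 4 (adjusted p = 0.0642 and 0.0536). Il15 did not pass without anti-gp120 replicates 1, 2, 3 or 4 (adjusted p = 0.0633, 0.104, 0.0710 and 0.118) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.101, 0.0786, 0.0715 and 0.0702). Ifngr1 did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.109, 0.0764 and 0.128) or anti-MerTK replicates 1, 2 or 3 (adjusted p = 0.112, 0.0995 and 0.102). Tgfbr1 did not pass without anti-gp120 replicates 2, 3 or 4 (adjusted p = 0.110, 0.0799 and 0.128) or anti-MerTK replicates 1, 2, 3 or 4 (adjusted p = 0.107, 0.0982, 0.102 and 0.0546). With length and GC offsets Tgfbr1 had an adjusted p of 0.0799 and Il15 of 0.0570.

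Type I interferon genes rose more than interferon gamma genes within the same libraries. The type I score minus the gamma score (25 members) was 0.58 ± 0.13 after anti-MerTK and -0.18 ± 0.16 after anti-gp120 (SD, n = 5), a difference of 0.75 (exact permutation p = 0.00794, the smallest possible). It lay between 0.37 and 0.72 in the 5 anti-MerTK libraries and between -0.43 and 0.02 in the 5 anti-gp120 libraries. A candidate explanation is a signal that acts mainly through the type I interferon receptor, but many genes answer both interferons and the ligand was not measured here beyond the low counts of Ifnb1.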
